A study of Mus musculus with 6 samples.

How the data were processed

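RNA from the media and intima of mouse aortas was measured in 6 libraries, 3 labelled ChemR23-deficient and 3 labelled control. The samples carry library names rather than replicate numbers, so replicates 1 to 3 are named in the order of deposition and pair nothing. Each library is taken as a separate sample of its group; where nothing says that each came from a separate animal, the p-values measure only the spread between these samples. Libraries were made with the TruSeq Stranded mRNA kit and sequenced as paired-end 50 bp reads on an Illumina NovaSeq instrument, per the labels' protocols. Per the submitters' processing notes the tools were bcl2fastq 2.20, HISAT2 2.2.1, featureCounts 2.0.1, DESeq2 1.36.0 and R 4.2.0, with the genome build GRCm38. The gene annotation and the strand setting of the counting are not given in the sources used here. Without the strand setting, reads of a gene cannot be told from those of a gene overlapping it on the other strand, and near-identical genes such as the globins may have split their reads.

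The deposited table holds, for 55487 genes, a signal per library that is never negative: gene read counts that the authors divided by one size factor per library, as the values show. It also holds the authors' log2 fold change and its standard error, their test score (the fold change over its error) and their p-value and adjusted p-value. Symbols were missing for 3422 genes, and 3304 of these were filled from a reference list by gene ID. In each of the 6 libraries 100% of the values above 0 were whole multiples, within 0.001, of the smallest one, so whole reads were recovered by dividing by it. In labelled-deficient replicate 3 and control replicate 3 this step was close to 1 (1.01 and 1.00). An automated check could not tell it there from rounding to whole numbers. A DESeq2 fit with a prior on fold changes was run on the recovered reads of all 6 libraries. It gave the deposited fold changes with the opposite sign (28288 genes, largest deviation 7.72e-07). Of 15771 adjusted p-values from that fit, 0 differed from the deposited ones by over 0.001. These values argue against a faulty recovery. The recovered totals were 30887855 to 38600604 reads per library. No 2 libraries agreed within sampling noise (chi-square per degree of freedom 30.6 to 135.7, r of 0.986 to 0.992 across genes).

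Because the table holds normalized values and not raw counts, the test planned for such values was the main one: limma 3.58.1 (lmFit, eBayes with trend) on log2(normalized count + 1), for the 20669 genes with a mean of at least 1 over all 6 libraries. P-values were two-sided and adjusted by the Benjamini-Hochberg method, and a gene was called at an adjusted p under 0.05. Log2 differences are labelled ChemR23-deficient minus labelled control on the log2(normalized count + 1) scale, which understates the change of genes with few counts. Errors beside means are SDs of normalized counts over 3 libraries, and SE is the moderated standard error of the log2 difference. Calculations ran in R 4.3.3 and Python 3.11.15. Gene positions come from the GENCODE annotation of GRCm38.

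Gene lists were tested with camera (limma) at a preset inter-gene correlation of 0.01, two-sided, adjusted over the 32 lists, all of which had at least 3 measured members, with fry beside it. The plan named log2 CPM for this test; the log2(normalized count + 1) values were used in its place. The lists were chemerin system, contractile smooth muscle, modulated smooth muscle, chondrogenic and osteogenic, macrophage, foam cell and lipid handling, T cell, B cell, neutrophil, endothelial, adventitial fibroblast, adipocyte, Schwann cell and nerve, erythroid, skeletal muscle, cardiac muscle, cholesterol synthesis, liver X receptor targets, inflammatory cytokine and adhesion, interferon-stimulated, MHC class II presentation, extracellular matrix, TGF-beta response, cell proliferation, nuclear oxidative phosphorylation, mitochondrially encoded, immediate early and heat shock, unfolded protein and integrated stress response, circadian clock, ribosomal protein, Hox position code and sex-linked genes. Some genes stand in more than 1 list, such as Spp1, Vcam1, Abca1, Dcn, Lum, Fabp4 and Pparg.

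The lists, tests and the rule for named genes were fixed before the data were examined. The rule takes Cmklr1, Rarres2, Ccrl2 and Gpr1; the sentinels Acta2, Myh11, Tagln, Cnn1, Myocd, Cd68, Adgre1, Lgals3, Cd36, Abca1, Klf4, Spp1, Vcam1 and Ly6a; the 8 largest rises and 8 largest falls among called genes with a mean of at least 1 and groups that do not overlap, leaving out predicted genes, Rik genes, pseudogenes and genes without a symbol; and from each list up to 3 called members with the lowest p or, where none was called, the 2 with the highest mean. Gpnmb, Trem2, Cd163, Lyve1, F13a1, Mrc1, Alas2, Itga2b, Tubb1, Gp9, Adipoq and Dbp were chosen after their values were seen. The result of 1 gene that the rule takes is not reported here.

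The limma test was tested on simulated counts drawn with the real means, library sizes and dispersions, with 200 changed genes among 20072. For the comparison of 3 with 3 libraries it called 73 of 100 genes changed 2-fold and 93 of 100 changed 4-fold, all with the right sign, and 16 unchanged genes. The changed genes were drawn from the more abundant ones, each gene was simulated independently, and no library was set apart within a group. These shares therefore need not hold for genes with few counts or for the real groups. Other settings chosen beforehand were pseudocounts (0.1 and 5), no filter, other thresholds, leaving out each library in turn, and count tests on the recovered reads with edgeR 4.0.16 (other scalings, filters and robust=TRUE), limma-voom and DESeq2 1.42.0. The plan also named edgeR with its TMM scaling as an added alternative where whole reads could be recovered. Chosen after seeing the data were other scalings and the stricter filter of the limma fit for single genes, and its TMM scaling for the lists. So were a covariate for Y-linked expression, the 4 libraries with Y-linked expression alone and DESeq2 with a prior on fold changes. The same holds for edgeR on the genes that limma tested. It also holds for camera with an estimated correlation in the fits of fewer libraries or with the covariate. The edgeR test on the recovered reads called 1 gene of 15196.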

Results

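RNA of the aortic media and intima, the layers left after the adventitia was stripped off under a microscope, was sequenced from 6 libraries of atherosclerosis-prone mice. All animals lacked Apoe, the apolipoprotein whose absence raises plasma cholesterol, and all had been irradiated and given Apoe-deficient marrow with an intact receptor gene. In 3 libraries the recipients were labelled as also carrying the e allele of ChemR23 on both chromosomes (here "labelled ChemR23-deficient"), and in 3 the recipients were labelled as lacking Apoe alone (here "labelled control"). ChemR23, encoded by Cmklr1, is a receptor for the adipokine chemerin and for a lipid mediator of inflammation resolution. The animals were transplanted at 8 to 10 weeks of age, rested for 4 weeks and fed a Western diet (21% fat, 0.15 to 0.2% cholesterol) for 6 weeks. Each library held 30887855 to 38600604 reads assigned to genes, recovered from the deposited normalized counts. The 10 most abundant genes took 9.2 to 10.8% of them.

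Cmklr1, the targeted gene (ENSMUSG00000042190, chromosome 5, 113612354 to 113650426, GRCm38), was not lower in the libraries labelled deficient. Its normalized count was 2388, 1788 and 1551 in the libraries labelled ChemR23-deficient and 1396, 1028 and 1720 in those labelled control, a mean of 1909 ± 431 against 1382 ± 346 (SD, n = 3 each). The log2 difference, labelled deficient minus labelled control, was 0.47 (SE 0.21, 95% interval -0.01 to 0.96, limma adjusted p = 0.427). The part of the gene that the e allele lacks is not given in the sources used here, and donor cells carried the intact gene, so a remaining signal checks little. All directions below are between the libraries as labelled. Rarres2, which encodes chemerin, differed by 0.19 (SE 0.08, limma adjusted p = 0.411) and Ccrl2, a chemerin-binding receptor without classical signalling, by -0.02 (SE 0.10, limma adjusted p = 0.961). Gpr1, another chemerin receptor, was close to the detection floor, at 1.90, 0 and 0 in the libraries labelled deficient and 0, 6.66 and 2.004 in those labelled control. Of the 4 measured chemerin system genes, 0 passed limma, over all genes or adjusted over the list alone. For 1 of them the unadjusted p was under 0.05, DESeq2 called 0, and the list was not called (median 0.09, mean -0.09, camera adjusted p = 0.566).

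Sex-linked genes differed within the group labelled deficient. Xist, the RNA that silences an X chromosome in female cells, was at 16080 and 13150 normalized counts in labelled-deficient replicates 1 and 2 and at 373 in replicate 3, against 8.87 to 22.0 in the controls. Ddx3y, a Y-linked RNA helicase, was at 8.55 and 0 in labelled-deficient replicates 1 and 2, at 6374 in replicate 3 and at 6058 to 6796 in the controls. Labelled-deficient replicates 1 and 2 thus had a female pattern, and the other 4 libraries a male one by Ddx3y. Xist in labelled-deficient replicate 3 still lay above that of all controls. In labelled-deficient replicate 2 the Y-linked genes Uty, Kdm5d and Eif2s3y were at 0 too. That library thus showed none of these genes, from recipient or donor cells. The labels state no sex of recipients or marrow donors, so cells of both sources cannot be told apart. The pattern also overlaps with the groups. Of the 5 measured sex-linked genes, 0 passed limma over all genes, while 1 was higher and 4 were lower adjusted over the list alone. All 5 had an unadjusted p under 0.05, DESeq2 called 1, and the list was not called (median -6.09, camera adjusted p = 0.225).

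**Figure D1:**
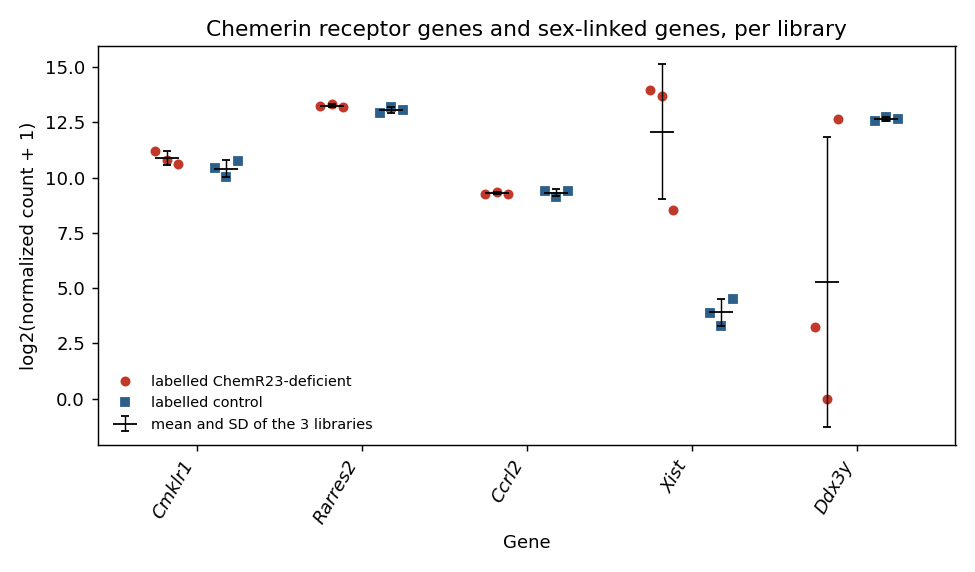
Each point is 1 library, as log2(normalized count + 1), for Cmklr1, Rarres2, Ccrl2, Xist and Ddx3y; circles are libraries labelled ChemR23-deficient, squares those labelled control, and bars the mean and SD of 3 libraries. Cmklr1 was not lower in the libraries labelled deficient (1551 to 2388 against 1028 to 1720 normalized counts). Ddx3y was at 8.55 and 0 in labelled-deficient replicates 1 and 2, against 6374 in replicate 3.

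The first comparison asked which genes differed between aortas labelled ChemR23-deficient and labelled control. The metallothionein genes Mt1 and Mt2, which encode metal-binding stress proteins and lie next to each other on chromosome 8, fell in the libraries labelled deficient. Mt1 went from 4383 ± 426 to 1974 ± 75.1 normalized counts (SD, n = 3 each), a log2 change of -1.15 (SE 0.08, 95% interval -1.34 to -0.95, limma adjusted p = 0.0194), and Mt2 from 1900 ± 340 to 804 ± 42.8 (log2 -1.23, SE 0.13, limma adjusted p = 0.045). Il1rn, which encodes the interleukin-1 receptor antagonist, rose from 41.2 ± 5.47 to 266 ± 79.5 (log2 2.63, SE 0.24, limma adjusted p = 0.0424). The neighbouring chromosome 8 genes of coagulation factors VII and X rose too. F7 (13026034 to 13035809) went from 8.76 ± 2.19 to 85.9 ± 39.1 and F10 (13037308 to 13056676) from 12.8 ± 2.76 to 73.7 ± 9.29, log2 changes of 3.08 (SE 0.39) and 2.45 (SE 0.27), both with limma adjusted p = 0.045.

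In all, 28 of 20669 genes tested passed limma, 15 higher and 13 lower in the libraries labelled deficient. The other large rises were in Lilrb4b (log2 1.78, SE 0.22), a leukocyte immunoglobulin-like receptor, Galnt6 (1.67, SE 0.16), an enzyme that starts mucin-type O-glycosylation, Nrep (1.39, SE 0.16), Smim5 (1.10, SE 0.14) and the synaptotagmin Syt15 (1.07, SE 0.13). The largest fall was in Hbb-bt, an adult beta-globin gene, from 34900 ± 15890 to 882 ± 727 normalized counts (log2 -5.52, SE 0.59). Cxcr2, a neutrophil chemokine receptor (log2 -3.35, SE 0.42), and Ppbp, a platelet chemokine (-3.26, SE 0.39), also fell. Sult1a1, a sulfotransferase, fell by 1.16 (SE 0.15) and Npy1r, a neuropeptide Y receptor, by 1.11 (SE 0.14) on the log2 scale. Each of these had limma adjusted p = 0.045. The rule that named the genes of this paragraph asked for groups that do not overlap. Over all genes tested such a gap was seen in 17.0%, where chance gives 10%.

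None of the 28 stayed called by limma when labelled-deficient replicate 1 or 2, or control replicate 1 or 2, was left out (0 genes called each, 1706 to 2540 at an unadjusted p under 0.05 against 2512 with all libraries), and without labelled-deficient replicate 3, 434 genes were called, all 28 among them. With labelled-deficient replicate 3 left out, the libraries remaining in its group had the female pattern and the controls the male one. Sex pattern and group then coincided and cannot be told apart, which holds wherever that replicate is left out below. Without control replicate 3, 7 genes were called, 4 of them shared. Over the fits with 1 library left out, some log2 changes moved little: -1.21 to -1.07 for Mt1, 2.40 to 2.75 for Il1rn, 2.29 to 2.58 for F10 and 1.55 to 1.78 for Galnt6. With a covariate for Y-linked expression limma called 0 genes (1485 at an unadjusted p under 0.05). That covariate takes up labelled-deficient replicates 1 and 2, so the group difference there rests on replicate 3 alone and is no comparison of 3 with 3 libraries. Without the covariate, edgeR called 1 gene, Mt1, also when given the 20669 genes that limma tested (adjusted p = 0.0337, a setting chosen after seeing the data), and DESeq2 called 713. Lilrb4b and Hbb-bt share sequence with close copies, and Galnt6, Lilrb4b, Mt2 and Sult1a1 overlap exons of other genes, so part of their counts may belong elsewhere.

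**Figure D2:**
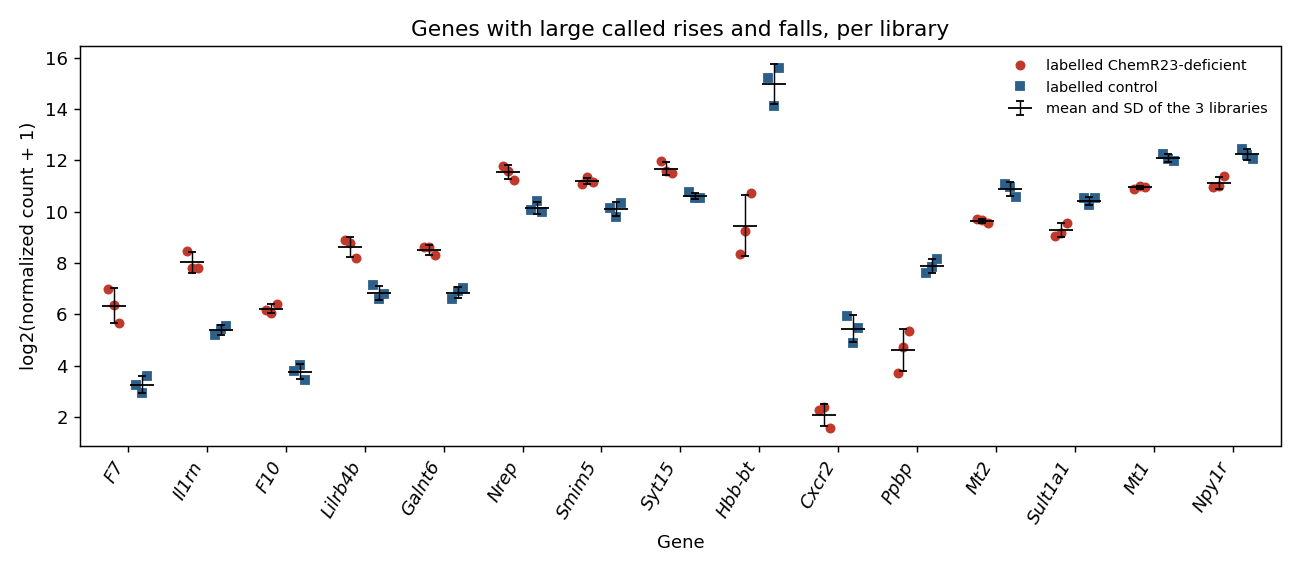
Log2(normalized count + 1) in each library for the 8 largest called rises and 7 of the 8 largest called falls; circles are libraries labelled ChemR23-deficient, squares those labelled control, and bars the mean and SD of 3 libraries. The genes were chosen by a rule that asks for groups that do not overlap and leaves out predicted genes, such as Gm43351 (log2 3.38). The largest difference shown was that of Hbb-bt (log2 -5.52).

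The authors' deposited table calls 691 genes, 27 of the 28 called by limma among them. The comparison is named treated and control, in that order, and its fold change column states no direction. For all 691 genes the sign is opposite to labelled deficient minus labelled control. A DESeq2 fit with a prior on fold changes gave the same values with the opposite sign (28288 genes compared, largest deviation 7.72e-07). If the name means treated over control, with the labelled-deficient group as treated, the name and the sample labels disagree in direction. Read by the labels, 406 of the 691 genes were higher and 285 lower in the libraries labelled deficient. In the authors' deposited table, in its own direction, Cmklr1 has a log2 fold change of -0.37 (adjusted p = 0.257), and Mt1 one of 1.08 (adjusted p = 1.31e-24).

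The second question, from the study's title, was whether smooth muscle genes and macrophage or foam cell genes differed. No gene of the contractile apparatus passed the test. Acta2, smooth muscle actin, was at 723400 ± 111000 against 625500 ± 38890 normalized counts (log2 0.20, SE 0.16, limma adjusted p = 0.676), and Myh11, smooth muscle myosin, at 273900 ± 57400 against 274700 ± 17030 (-0.02, SE 0.16, 0.972). Tagln differed by 0.07 (SE 0.12, limma adjusted p = 0.874) and Cnn1 by 0.21 (SE 0.11, limma adjusted p = 0.507), with 95% intervals that stayed between -0.22 and 0.47. Myocd, the coactivator that drives contractile genes, was at 4144 ± 1216 against 7297 ± 1181 (log2 -0.84, SE 0.20, limma adjusted p = 0.155). Of 22 contractile smooth muscle genes 0 passed limma over all genes and 2 were lower adjusted over the list alone. For 3 the unadjusted p was under 0.05, DESeq2 called 2 lower, and the list was not called (median 0.07, mean -0.01, camera adjusted p = 0.566). Among the 4 libraries with Y-linked expression, of which 1 is labelled deficient, its median was 0.23 (camera adjusted p = 2.77e-04; adjusted p = 0.641 with an estimated correlation). Without labelled-deficient replicate 2 it was 0.17 (camera adjusted p = 0.00984; adjusted p = 0.784 with an estimated correlation), and without labelled-deficient replicate 3 it turned to -0.033 (camera adjusted p = 0.296).

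Genes of modulated smooth muscle were not called as a list by camera, which tests for a common direction, while fry for changes in either direction gave an adjusted p = 0.00171. Spp1, which encodes osteopontin, was at 4823 ± 3045 against 486 ± 268 normalized counts (log2 3.33, SE 0.57, limma adjusted p = 0.0765), Vcam1 differed by 0.42 (SE 0.21, limma adjusted p = 0.48), Klf4 by -0.09 (SE 0.14, 0.856) and Ly6a by -0.20 (SE 0.28, 0.829). The most abundant members, Bgn and Fn1, both matrix genes, differed by 0.18 (SE 0.10) and -0.24 (SE 0.12). Of 22 measured members 0 passed limma over all genes, and 5 were higher and 2 lower adjusted over the list alone. DESeq2 called 5 higher and 1 lower, 9 had an unadjusted p under 0.05, and the list median was 0.15 (camera adjusted p = 0.138). That median was 0.018 without labelled-deficient replicate 1, 0.039 without control replicate 1 and 0.323 without labelled-deficient replicate 3. Among the 4 libraries with Y-linked expression it was -0.054 (camera adjusted p = 0.555). Of 15 chondrogenic and osteogenic genes, which include Spp1 and Cytl1 (log2 0.02, SE 0.12), 0 passed limma over all genes and 2 were higher adjusted over the list alone. DESeq2 called 2, 6 had an unadjusted p under 0.05, and the median was 0.02 (camera adjusted p = 0.572; fry in either direction, adjusted p = 0.00171). That median was -0.085 without control replicate 2 and 0.139 without control replicate 3.

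Foam cell and lipid handling genes were higher as a list in the libraries labelled deficient, with 19 of 23 members above 0 and a median log2 difference of 0.68 (camera adjusted p = 5.18e-06). With an estimated correlation the adjusted p = 0.725. The lysosomal protease Ctsb was at 50830 ± 14290 against 29940 ± 3174 normalized counts (log2 0.73, SE 0.20, limma adjusted p = 0.208) and the tetraspanin Cd9 differed by 0.17 (SE 0.07, limma adjusted p = 0.375). The fatty acid transporter Cd36 differed by -0.22 (SE 0.77) and the cholesterol exporter Abca1 by 0.64 (SE 0.28, limma adjusted p = 0.425). Of the 23 members 0 passed limma over all genes and 10 were higher adjusted over the list alone; unadjusted p was under 0.05 for 14, and DESeq2 called 11 higher. The list medians per library, relative to the control mean, were 0.89 and 1.08 in labelled-deficient replicates 1 and 2, which had the female pattern, and 0.19 in replicate 3, against -0.07 to 0.11 in the controls. Among the 4 libraries with Y-linked expression the list was not called (median 0.19, camera adjusted p = 0.0914).

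Macrophage genes were highest in labelled-deficient replicates 1 and 2, with list medians relative to the control mean of 1.15 and 1.75. Replicate 3, at -0.18, lay within the range of the controls (-0.60, 0.49 and 0.05). Cd68, a lysosomal macrophage protein, was at 1807, 2050 and 572 normalized counts in the libraries labelled deficient and 256 to 321 in the controls (log2 2.11, SE 0.43, limma adjusted p = 0.115). Lgals3, which encodes galectin-3, was at 3714 ± 1491 against 1014 ± 123 (log2 1.78, SE 0.30, limma adjusted p = 0.0751), and Lyz2, lysozyme, at 15240 ± 10570 against 3381 ± 1277 (1.89, SE 0.59, 0.258). Adgre1, which encodes F4/80, differed by 0.28 (SE 0.41, limma adjusted p = 0.841) and the efferocytosis receptor Mertk by -0.21 (SE 0.08, 0.334). The 24 macrophage genes were higher as a list (17 above 0, median 0.87, camera adjusted p = 0.032), with adjusted p = 0.771 with an estimated correlation. Of them 0 passed limma over all genes, and 5 were higher and 2 lower adjusted over the list alone. Unadjusted p was under 0.05 for 14, and DESeq2 called 4 higher and 1 lower. Among the 4 libraries with Y-linked expression the median turned to -0.18 (camera adjusted p = 0.583), and the call was also lost without labelled-deficient replicate 1 (median 0.69) or 2 (0.33) or control replicate 1 (0.54) or 3 (0.93). Without labelled-deficient replicate 3, where sex pattern and group coincided, the median rose to 1.45.

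**Figure D3:**
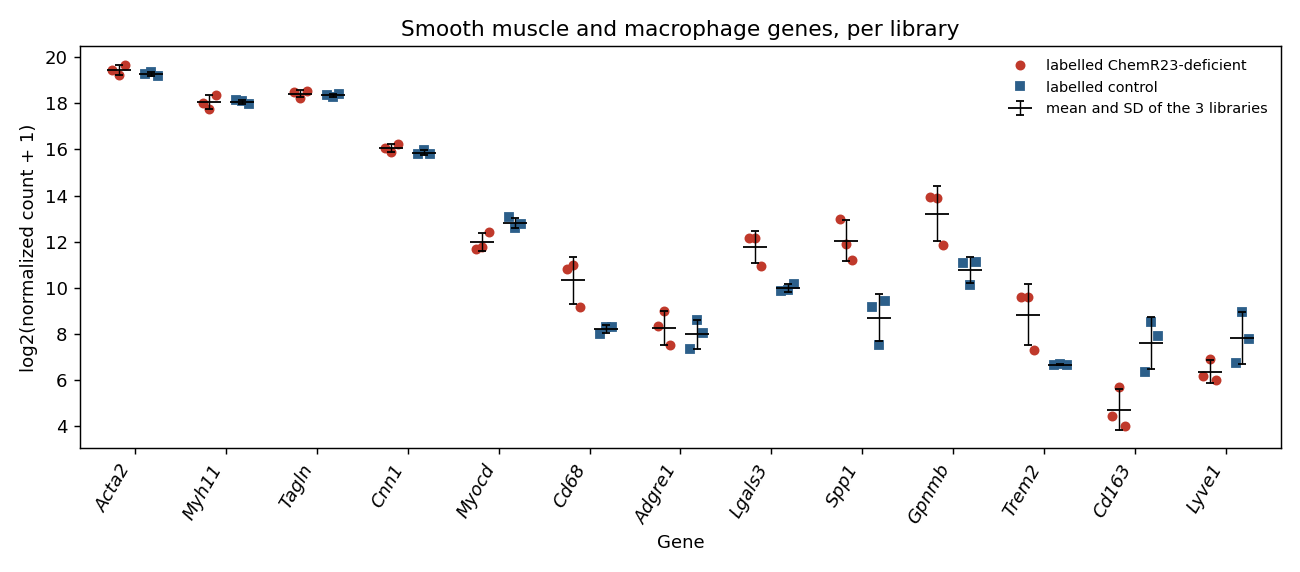
Log2(normalized count + 1) in each library for contractile genes (Acta2 to Myocd) and genes of the macrophage list (Cd68, Adgre1, Lgals3, Cd163 and Lyve1). Spp1, of the modulated smooth muscle list, and Gpnmb and Trem2, of the foam cell list, are shown too. Circles are libraries labelled ChemR23-deficient, squares those labelled control, and bars the mean and SD of 3 libraries. Labelled-deficient replicate 3 lay below the other libraries of its group for Cd68 (572 against 1807 and 2050 normalized counts).

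Inflammatory cytokine and adhesion genes were higher as a list, with 18 of 23 members above 0 (median 0.42, camera adjusted p = 6.99e-04) and adjusted p = 0.725 with an estimated correlation. Il1rn, the 1 member that passed limma over all genes, encodes an antagonist of interleukin-1 and not a cytokine that signals; 5 members were higher adjusted over the list alone. Without labelled-deficient replicate 3, where sex pattern and group coincided, the list median was 0.635. Targets of the liver X receptor, which senses oxidized cholesterol, were also higher as a list (8 of 11 above 0, median 0.27, camera adjusted p = 0.0407; adjusted p = 0.725 with an estimated correlation). Among them the desaturase genes went apart, Scd2 by 0.47 (SE 0.10, limma adjusted p = 0.119) and Scd1 by -1.41 (SE 0.87, limma adjusted p = 0.581). The call of this list was lost without labelled-deficient replicate 1 (median 0.239) or 2 (0.296) or control replicate 1 (0.177) or 3 (0.134), and among the 4 libraries with Y-linked expression its median was -0.085 (camera adjusted p = 0.868). Of these 11 genes 0 passed limma over all genes, 3 were higher adjusted over the list alone, 3 had an unadjusted p under 0.05, and DESeq2 called 2. Cholesterol synthesis genes, such as Srebf2 (-0.12, SE 0.13) and Hmgcs1 (0.00, SE 0.18), were not called (22 members, median -0.01, camera adjusted p = 0.815). Of these, 0 passed limma, over all genes or adjusted over the list alone, 1 had an unadjusted p under 0.05, and DESeq2 called 0.

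Extracellular matrix genes were higher as a list in the libraries labelled deficient, 21 of 25 above 0 with a median of 0.29 (camera adjusted p = 7.15e-06; adjusted p = 0.725 with an estimated correlation). Eln, which encodes elastin, was at 142200 ± 23090 against 90830 ± 22370 normalized counts (log2 0.66, SE 0.19, limma adjusted p = 0.226) and Sparc, a collagen-binding glycoprotein, at 91090 ± 11310 against 64380 ± 5063 (0.50, SE 0.12, 0.154). Of the 25 members 0 passed limma over all genes, and 12 were higher and 3 lower adjusted over the list alone. Unadjusted p was under 0.05 for 16, and DESeq2 called 9 higher. Cell proliferation genes were higher as a list as well (17 of 22 above 0, median 0.38, camera adjusted p = 7.29e-04; adjusted p = 0.725 with an estimated correlation), although the most abundant members Mcm6 (0.07, SE 0.12) and Pcna (-0.01, SE 0.08), both of DNA replication, differed little. Of these 22 genes 0 passed limma, over all genes or adjusted over the list alone; 7 had an unadjusted p under 0.05, and DESeq2 called 0. The call of the proliferation list was lost without control replicate 1 (median 0.232, camera adjusted p = 0.0645) and among the 4 libraries with Y-linked expression (median 0.151, camera adjusted p = 0.215).

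Genes of blood cells were lower in the libraries labelled deficient. All 8 measured erythroid genes were below 0 (median log2 difference -4.98, camera adjusted p = 1.66e-10; adjusted p = 0.714 with an estimated correlation), Hbb-bt fell over all genes tested and 8 were lower adjusted over the list alone. Globin transcripts took 0.005 to 0.031% of reads in the libraries labelled deficient and 0.269 to 0.829% in those labelled control. Neutrophil genes were lower as a list (9 of 10 below 0, median -2.41, camera adjusted p = 6.05e-06; adjusted p = 0.676 with an estimated correlation), with Cxcr2 fallen over all genes and 5 lower adjusted over the list alone. Among the 4 libraries with Y-linked expression the neutrophil median was -0.72 (camera adjusted p = 0.00113; adjusted p = 0.641 with an estimated correlation). B cell genes were lower too (10 of 11 below 0, median -1.37, camera adjusted p = 4.75e-06; adjusted p = 0.725 with an estimated correlation), yet the abundant members Ighm and Cd22 went apart, by -0.62 (SE 0.30) and 1.21 (SE 0.57). Of the B cell genes 0 passed limma over all genes and 9 were lower adjusted over the list alone; 9 had an unadjusted p under 0.05, and DESeq2 called 6. T cell genes were not called (13 members, median -0.29, camera adjusted p = 0.494), with Il7r, an interleukin receptor subunit, at 1.94 (SE 0.46, limma adjusted p = 0.159) and Thy1 at -0.18 (SE 0.55). Of these 0 passed limma over all genes and 1 was higher adjusted over the list alone; 3 had an unadjusted p under 0.05, and DESeq2 called 2.

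Adipocyte and adventitial fibroblast genes, of the tissue around the vessel, were lower as lists. All 18 adipocyte genes were below 0 (median -1.71, camera adjusted p = 3.73e-04; adjusted p = 0.725 with an estimated correlation). Cfd, which encodes adipsin, was at 55.1, 4807 and 3.03 normalized counts in the libraries labelled deficient and 1080, 22980 and 4435 in the controls (log2 -5.54, SE 2.31, limma adjusted p = 0.397), and Fabp4, an adipocyte fatty acid binding protein, differed by -1.86 (SE 0.81). Of these 18 genes 0 passed limma over all genes and 1 was lower adjusted over the list alone; 7 had an unadjusted p under 0.05, and DESeq2 called 1. The adipocyte median was -0.977 without labelled-deficient replicate 1, -3.686 without labelled-deficient replicate 2 and -2.822 without control replicate 3. Without control replicate 2 it was -0.932 and the call was lost (camera adjusted p = 0.0718). Adventitial fibroblast genes were lower as a list (10 of 15 below 0, median -0.30, camera adjusted p = 0.009; adjusted p = 0.725 with an estimated correlation), with Dcn, decorin, at -0.93 (SE 0.18, limma adjusted p = 0.101) and Gsn, gelsolin, at 0.01 (SE 0.14). Of these 15 genes 0 passed limma over all genes and 3 were lower adjusted over the list alone; 6 had an unadjusted p under 0.05, and DESeq2 called 2. The adventitial call was lost without labelled-deficient replicate 1 (median -0.249) or 3 (-0.207) or control replicate 2 (-0.231) or 3 (-0.351), and the median was -0.536 without labelled-deficient replicate 2.

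Ribosomal protein genes were lower by a small amount (26 of 26 below 0, median -0.13, camera adjusted p = 1.75e-04; adjusted p = 0.725 with an estimated correlation), Rpl4 by -0.13 (SE 0.07) and Rpl7 by -0.06 (SE 0.07). Of these 0 passed limma, over all genes or adjusted over the list alone; 4 had an unadjusted p under 0.05, and DESeq2 called 0. With this list, 12 of the 32 gene lists were called by camera with its preset correlation of 0.01, 6 higher and 6 lower. None of the 32 was called with an estimated correlation, where the smallest adjusted p was 0.676, or by fry for a common direction, where the smallest was 0.0744; fry for changes in either direction called 9, namely modulated smooth muscle, chondrogenic, inflammatory, neutrophil, cardiac muscle, extracellular matrix, erythroid, B cell and TGF-beta response genes. In fits with 1 library left out, or by Y-linked expression, camera called 9 to 15 lists with its preset correlation and 0 with an estimated one (smallest adjusted p = 0.234 with an estimated correlation, without control replicate 3).

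**Figure D4:**
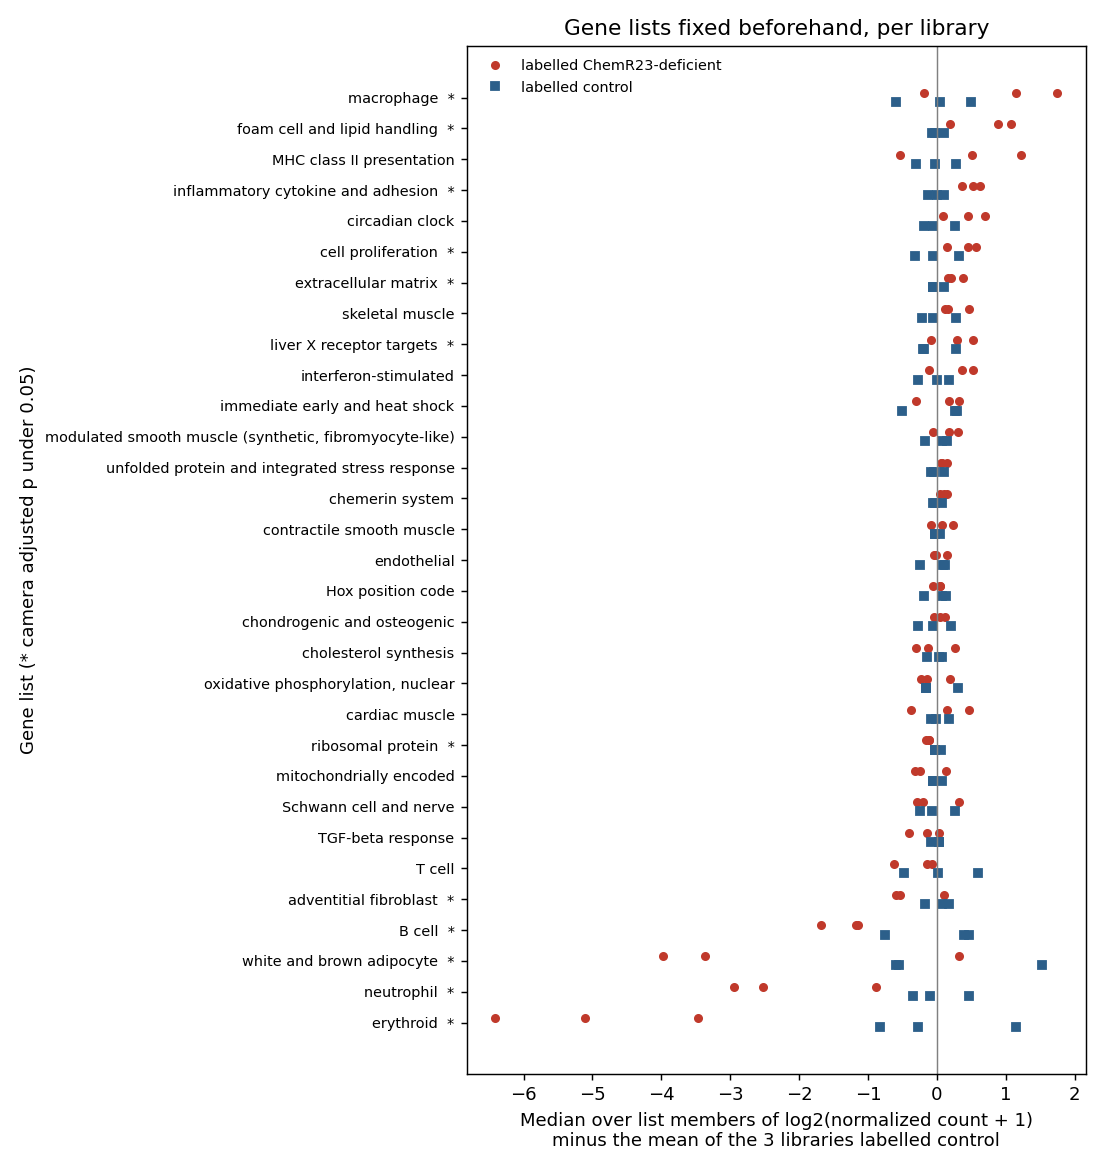
For each gene list except the sex-linked one, the median over members of log2(normalized count + 1) minus the mean of the libraries labelled control, with 1 point per library (circles labelled ChemR23-deficient, squares labelled control). The erythroid list lay at -6.41, -5.11 and -3.47 in the libraries labelled deficient and at -0.83, -0.28 and 1.15 in those labelled control.

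The other lists were not called by camera, although fry for changes in either direction called TGF-beta response (adjusted p = 0.038) and cardiac muscle genes (adjusted p = 0.00474). In the TGF-beta response list (14 members, median -0.26, camera adjusted p = 0.494) Bhlhe40, a transcriptional repressor of the clock and hypoxia responses, rose from 682 ± 107 to 1268 ± 60.6 normalized counts (log2 0.90, SE 0.12, limma adjusted p = 0.0455), and 2 members were higher and 2 lower adjusted over the list alone. Clock genes had a median of 0.41 (15 members, camera adjusted p = 0.172), with the repressor Nr1d1 at 0.70 (SE 0.23) and Tef at 0.41 (SE 0.22). Members of the unfolded protein and integrated stress response list had a median of 0.09 (16 members, camera adjusted p = 0.0501), with the chaperones Hsp90b1 at 0.22 (SE 0.07) and Hspa5 at 0.21 (SE 0.12). Genes of MHC class II presentation had a median of 0.45 (7 members, camera adjusted p = 0.105), with the invariant chain Cd74 at 0.44 (SE 0.45) and H2-Aa at 0.45 (SE 0.41). The interferon-stimulated genes had a median of 0.24 (20 members, camera adjusted p = 0.0984), with Ifi27l2a at -1.09 (SE 1.01) and Gbp2 at 0.32 (SE 0.13). Endothelial genes stood at a median of 0.04 and a mean of -0.03 (16 members, camera adjusted p = 0.819), with Pecam1 at -0.13 (SE 0.16) and Vwf at -0.42 (SE 0.22).

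Nuclear oxidative phosphorylation genes had a median of -0.04 (25 members, camera adjusted p = 0.595), Atp5b differing by -0.07 (SE 0.16) and Atp5a1 by -0.03 (SE 0.12), and mitochondrially encoded genes one of -0.14 (13 members, camera adjusted p = 0.0589), mt-Co1 differing by -0.23 (SE 0.17) and mt-Cytb by -0.18 (SE 0.16). Immediate early and heat shock genes had a median of 0.17 but a camera direction of lower (19 members, camera adjusted p = 0.867), with Dusp1 at 0.55 (SE 0.27) and Klf6 at -0.27 (SE 0.14). Schwann cell and nerve genes stood at -0.15 (12 members, camera adjusted p = 0.689), Pmp22 at 0.42 (SE 0.08, limma adjusted p = 0.109) and Prx at -0.11 (SE 0.09). Skeletal muscle genes stood at 0.28 (9 members, camera adjusted p = 0.225), Casq1 at 0.83 (SE 0.41) and Tnnt3 at -0.01 (SE 0.36). Cardiac muscle genes had a median of -0.04 and a mean of 0.26 (10 members, camera direction higher, camera adjusted p = 0.699), Ryr2 at -0.30 (SE 0.11) and Tnnt2 at -0.79 (SE 0.20, limma adjusted p = 0.173). The Hox position code, which reflects the level of the body axis, stood at 0.03 with a mean of -0.20 (25 members, camera direction higher, camera adjusted p = 0.689), Hoxa7 at -0.07 (SE 0.14) and Hoxb3 at 0.22 (SE 0.11).

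Among members of these last 13 lists, Bhlhe40 was the 1 gene that passed limma over all genes. Adjusted over the list alone, 1 Schwann cell gene, 1 cardiac gene and 1 clock gene were higher, and 2 cardiac genes, 1 interferon-stimulated gene and 1 clock gene were lower. Unadjusted p was under 0.05 for 7 TGF-beta response, 6 cardiac muscle, 5 clock, 5 interferon-stimulated, 5 Hox, 3 stress response, 3 Schwann cell, 2 endothelial, 1 immediate early and 1 mitochondrially encoded genes, and for 0 genes of MHC class II presentation, skeletal muscle and nuclear oxidative phosphorylation. DESeq2 called 1 to 4 members of 9 of the 13 lists and 0 of MHC class II presentation, skeletal muscle, nuclear oxidative phosphorylation and mitochondrially encoded genes. The edgeR test with its TMM scaling and filter, and limma-voom, called 0 members of any of the 32 lists. Without its filter edgeR called 388 genes, all 28 called by limma among them, which include the list members Hbb-bt, Cxcr2, Il1rn and Bhlhe40.

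Some lists not called with all libraries were called by camera in the settings below, each with adjusted p = 0.559 or more with an estimated correlation. Without labelled-deficient replicate 3, genes of MHC class II presentation (median 0.937, camera adjusted p = 5.33e-05) and interferon-stimulated genes (0.49, 3.97e-04) were called higher, and cholesterol synthesis (-0.193, 0.00123) and sex-linked genes (-9.129, 5.78e-04) lower. With that replicate left out, sex pattern and group coincided, so these calls cannot be assigned to either. The 4 libraries with Y-linked expression, of which that replicate is the only one labelled deficient, gave the opposite call for cholesterol synthesis (0.274, 7.06e-06) and MHC class II genes (-0.539, 0.00864). There, clock (0.703, 0.0109) and skeletal muscle genes (0.456, 0.0419) were called higher and mitochondrially encoded genes lower (-0.248, 7.38e-04). These calls with 1 labelled-deficient library describe that library and not its group. Mitochondrially encoded genes were also called lower without labelled-deficient replicate 2 (-0.339, 8.35e-06). Nuclear oxidative phosphorylation genes were called lower without that replicate (-0.157, 0.0187) and with the covariate for Y-linked expression (-0.228, 0.0496), but higher without control replicate 2 (0.12, 0.041). Stress response genes were called higher without control replicate 2 (0.136, 0.00183) and interferon-stimulated genes without control replicate 1 (0.362, 0.0211). The median of MHC class II genes was -0.001 without labelled-deficient replicate 2, that of mitochondrially encoded genes -0.056 without labelled-deficient replicate 1, and that of clock genes 0.254 without control replicate 2.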

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

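For single genes the stricter filter and the other scalings of the limma fit, for lists its TMM scaling, and for both the settings by Y-linked expression were chosen after seeing the data. So were the edgeR test on the genes that limma tested, DESeq2 with a prior and an estimated correlation in fits of fewer libraries or with the covariate. Against 15 higher and 13 lower genes, edgeR called 0 and 1 with TMM, RLE and total-count scaling, with CPM of at least 1 in 3 libraries, with robust=TRUE and on the 20669 genes that limma tested, 0 and 0 with upper-quartile scaling, and 226 and 162 without its filter. Limma-voom called 0 and 1, DESeq2 413 and 300, and DESeq2 with a prior 406 and 285. Within limma, a pseudocount of 0.1 gave 1 and 1, no filter 40 and 51, CPM of at least 1 in 3 libraries 0 and 1, total-count scaling 8 and 11, an adjusted p under 0.1 83 and 85, and an absolute log2 fold change of at least 1 9 and 11. A covariate for Y-linked expression, or the 4 libraries with it alone (in both, the difference rests on the lone labelled-deficient library), gave 0 and 0, with 1485 and 1285 genes at an unadjusted p under 0.05. Leaving out 1 library gave 0 to 303 higher and 0 to 131 lower genes. The cause was not tested. Cmklr1 kept its direction and missed the threshold in all settings run (log2 0.20 to 0.65).

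Of the lists, 6 were called higher and 6 lower, against 0 and 0 with an estimated correlation and 0 and 0 with fry. Foam cell genes (median 0.68) had adjusted p = 0.725 with an estimated correlation and 0.444 with fry, and a median of 0.186 (adjusted p = 0.059 and 0.0914) by Y-linked expression; macrophage genes (median 0.867) had 0.771 with an estimated correlation and 0.656 with fry. The medians over the leave-one-out fits were 0.486 to 0.978 for foam cell, 0.33 to 1.45 for macrophage and -0.033 to 0.165 for contractile genes, which reached 0.232 by Y-linked expression. With either setting by Y-linked expression, camera's direction and the median turned to -0.176 for macrophage, 0.274 for cholesterol synthesis, -0.539 for MHC class II, -0.037 for endothelial, -0.118 for interferon-stimulated, 0.026 for TGF-beta response and 0.015 for sex-linked genes. Of these, cholesterol synthesis (adjusted p = 2.37e-06 and 7.06e-06) was then called higher and MHC class II (0.0197 and 0.00864) lower. For these calls the adjusted p = 0.556 and 0.641 with an estimated correlation for cholesterol synthesis and 0.676 and 0.641 for MHC class II. Without labelled-deficient replicate 3, where sex pattern and group coincided, they were called the other way (camera adjusted p = 0.00123 and 5.33e-05). With an estimated correlation the adjusted p = 0.559 for both. By Y-linked expression the median alone turned for modulated smooth muscle (-0.054), liver X receptor (-0.085) and cardiac muscle genes (0.471 and 0.352), and the direction alone for immediate early genes (median 0.318). The direction also turned with the stricter filter for T cell (median -0.177) and cardiac muscle genes (-0.091), and without a filter for cardiac muscle genes (-0.075).

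Signs of single genes, none of them called in either fit, turned by Y-linked expression for Myh11 (0.29), Adgre1 (-0.48), Abca1 (-0.08), Cd22 (-0.08), Gsn (-0.11), Tnnt3 (0.72), Srebf2 (0.15), Hmgcs1 (0.25), Cd74 (-0.60), H2-Aa (-0.54) and Klf6 (0.06). Other turns were of genes near 0: Myh11 and Hmgcs1 (both 0.01) with upper-quartile scaling in edgeR, Cytl1 (0.00) with total-count scaling in edgeR, Gsn (-0.02 to 0.00) and Tnnt3 (0.04 to 0.09) with most count tests, at -0.01 for Gsn and 0.08 for Tnnt3 in edgeR and DESeq2, 0.06 for Tnnt3 with total counts, and Gsn also at -0.01 with total-count scaling in limma.

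Over the leave-one-out fits the direction turned at least once for the lists contractile (median -0.033 to 0.165), T cell (-0.512 to -0.064), endothelial (-0.064 to 0.084), Schwann cell (-0.379 to -0.022), cardiac muscle (-0.267 to 0.302), cholesterol synthesis (-0.193 to 0.099), oxidative phosphorylation (-0.157 to 0.12), immediate early (-0.161 to 0.279) and Hox (-0.026 to 0.093). It did so for Ccrl2 (-0.11 to 0.03), Myh11 (-0.18 to 0.12), Adgre1 (-0.07 to 0.67), Cd36 (-0.87 to 0.56), Klf4 (-0.22 to 0.07), Ly6a (-0.40 to 0.13), Cytl1 (-0.11 to 0.10), Thy1 (-0.63 to 0.39), Gsn (-0.10 to 0.15), Tnnt3 (-0.38 to 0.25), Hmgcs1 (-0.13 to 0.17), Ifi27l2a (-2.05 to 0.04), Cd74 (0.00 to 0.96), Mcm6 (0.00 to 0.20), Pcna (-0.04 to 0.04), Atp5b (-0.21 to 0.11), Atp5a1 (-0.14 to 0.09), Hoxa7 (-0.20 to 0.05) and Mrc1 (-1.03 to 0.17). Depth ran from 30887855 to 38600604 recovered reads per library.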

Other observations

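The splits of the libraries and the settings named beforehand aside, the tests in this part were chosen after the results were seen. In the libraries labelled deficient, Gpnmb and Trem2, expressed by lipid-laden macrophages, stood at 15530, 15070 and 3714 and at 781, 790 and 158 normalized counts, against 1106 to 2239 and 99.2 to 103 in the controls (log2 2.45 and 2.17, limma adjusted p = 0.137 and 0.185). Other genes of the macrophage list, picked because they fell, did not pass limma: Cd163 by -2.88 (adjusted p = 0.122), Lyve1 by -1.46 (0.318), F13a1 by -1.03 (0.37) and Mrc1 by -0.44 (0.851), which turned in sign with 1 library left out (-1.03 to 0.17). Adipoq, which encodes adiponectin, ranged over libraries of both groups, at 13.3, 1711 and 1.01 in the libraries labelled deficient and 575, 5082 and 1010 in the controls. The clock output gene Dbp was at 1797 to 3828 normalized counts against 391.5 to 2348 (log2 1.79, limma adjusted p = 0.293). Of the 319 genes tested within 10 Mb of Cmklr1, 35 (11%) had an unadjusted limma p under 0.05, against 12.2% of genes elsewhere, and 0 were called. In labelled-deficient replicate 3, which had the male pattern, Xist stood at 2.55% of the mean of replicates 1 and 2.

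With 10 ways to split 6 libraries into 3 and 3, no share under 0.05 can be had. The labelled split gave 28 called genes, a number that 1 split reached, itself included, and the highest other gave 4. For gene lists the labelled split gave 12 called by camera, a number that 3 splits reached, and the highest other gave 13.

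Foam cell and lipid handling genes were higher in the libraries labelled deficient (median log2 0.68). More adipose tissue in those samples runs against the adipocyte list, whose median was -1.705 with all 18 members below 0, and -3.686 to -0.932 with 1 library left out (13 below 0 without control replicate 2, where the call was lost). The difference did not rest on 1 library, since the lowest median with a library left out was 0.486. The sex of the animals cannot be told apart from the group: against the male-pattern controls, the only male-pattern library labelled deficient had a median difference of 0.186 and the female-pattern libraries one of 0.978. In that male-pattern library 11 of the 23 members lay above all 3 controls, where chance gives 25% of genes, but members of a list move together. An effect of the receptor in recipient cells may stand beside one of sex, and 1 library is too few to weigh them. Donor marrow carried the intact gene in both groups. The male-pattern library labelled deficient also held more Xist than the controls (373 against 8.87 to 22.0 normalized counts). It may therefore hold some female cells, and its comparison with the controls need not be free of sex. The sex of the marrow donors is not given in the labels.

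Erythroid genes were lower in the libraries labelled deficient (median log2 -4.98). Globin RNA made by vascular cells would leave other erythroid genes in place, yet a list of 9 such genes had a median of -3.64, with 8 below 0; Alas2, the erythroid enzyme of haem synthesis, was at 59.8 to 542 normalized counts against 3563 to 14290. Residual blood would bring platelet RNA too, and a list of 12 platelet genes, of which Pf4 is also in the macrophage list, had a median of -2.912 with 11 below 0, Itga2b at 34.4 to 73.4 against 205 to 273, Tubb1 at 0.95 to 10.8 against 78.3 to 149 and Gp9 at 5.70 to 14.0 against 68.0 to 106. These values go with less blood in the aortas of the libraries labelled deficient. B cell genes were not traced to that source: control replicate 3, which had the most globin reads (0.829%), had the lowest B cell median of the controls (-0.76 against 0.46 and 0.40). Neutrophil medians ran in the order of the erythroid ones in the libraries labelled deficient (-2.95, -2.52 and -0.88 against -6.41, -5.11 and -3.47). In the controls they did not (0.47, -0.35 and -0.1 against -0.83, -0.28 and 1.15). With 3 libraries per group such an order decides little, and the platelet list was weighed by its group difference alone. Less blood was thus neither shown nor excluded as the source of the lower neutrophil and B cell genes. A biological difference in blood cells between the groups was not tested.

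The deposited fold changes, from a comparison named treated and control, run opposite to labelled deficient minus labelled control. If the labels of the groups had been exchanged, Cmklr1 would be expected to be higher in the libraries labelled deficient, and it was so by 0.47 on the log2 scale, but with a 95% interval of -0.01 to 0.96 that reaches 0. An exchange of labels therefore cannot be told apart here from a comparison taken as control over deficient. Donor cells carry the intact gene, and the missing part of the e allele is not given in the sources used here. If the labels were exchanged, every direction given above could turn, with its size unchanged.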
